A study of Caenorhabditis elegans with 4 samples.

How the data were processed

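Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mixed-sex Caenorhabditis elegans embryos that carry an integrated transgene encoding the Hox transcription factor MAB-5 fused to EGFP and an epitope tag. Per the labels' protocols, worms were grown at 20 °C and crosslinked with 2% formaldehyde, chromatin was sonicated, and MAB-5::GFP was precipitated with affinity-purified anti-GFP antibodies. Part of each lysate was kept as input DNA. The 4 samples form a ChIP group and an input group of 2 replicates each. The labels do not say whether replicates came from separate cultures, and the p-values given here measure spread over peaks, not between cultures. The input samples were not analysed here, because the 3 files used hold a peak list for each ChIP replicate and 1 combined list for the series.

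Per the file headers and the source column, the peaks were called with SPP, passed through the irreproducible discovery rate procedure (IDR) and given in coordinates of WormBase build WS220. The aligner, tool versions, score thresholds and the way the combined list was drawn from both replicates are not given in the sources used here. For each peak the authors deposited a start, an end, a score and a running peak number. The unit of the deposited score is not named in the file headers. It has a top value shared by the strongest peaks of each list (473 peaks in replicate 1, 275 in replicate 2 and 272 in the combined list). The value of 10 to the power of minus this top score, times the number of peaks that share it, was 0.501 in both replicate lists and 0.480 in the combined list, a pattern that −log10 of a false discovery rate with a lowest attainable value would give. Scores were therefore used to rank peaks within a list and, beyond ranks, only in Pearson's r of the log scores, which depends on the capped scale. Peaks with equal scores were ordered by the authors' peak number. The peak number followed the score closely in the replicate lists (Spearman rho of -1.00 after rounding in each). In the combined list rho was -0.95, where 272 of 644 peaks were tied at the top score. Ties on that scale by themselves keep rho from reaching -1.00. Read depth is unknown from these lists. All intervals given here cover counting error over peaks only.

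Lists were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks counted as shared when they overlapped by at least 1 bp. Agreement of the replicates was measured on lists of equal length, the 644 highest scoring peaks of each, where 644 is the length of the combined list. Chance was measured by placing the replicate 2 peaks at random within their own chromosomes 1000 times, a permutation test of positions whose one-sided p is no smaller than 0.001. Correlations of scores were taken across peaks, which are not independent replicates, with a two-sided permutation p from 100000 resamples. Peaks per chromosome were tested against the chromosome's share of the length by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 6 chromosomes. The length of a chromosome was taken as the largest peak end in either replicate list, in place of the planned assembly length, since no sequence of build WS220 was used here. Shares carry 95% exact (Clopper-Pearson) intervals. The position of a peak was the midpoint of its interval. Tests of peak spacing counted an interval listed more than once as 1 peak.

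The comparisons of replicates and of chromosomes, the central 33.3% of each autosome and their tests were fixed before the data were examined. The tests of close peaks and of dense blocks, the replicate lists as background, and all alternatives for the central part were added afterwards. Planned results that need gene positions or sequence in WS220 coordinates were not run: position relative to genes, gene lists, motif occurrence and the mab-5 locus. The gene table at hand belongs to assembly WBcel235, and coordinates of different builds were not mixed. Binding regions are therefore named by position, and no gene is assigned to a peak. The rule for named genes covered Hox genes and cofactors, the genes nearest to the 10 highest scoring combined peaks, and at most 4 bound genes of each other list. Of it, only the 10 peaks themselves could be taken, and other positions named here were chosen after their values were seen.

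The tests of overlap, chromosomes, the central part, close peaks and score correlation were tested on simulated lists of 644 peaks. The densest-window test was not. With 200 shared peaks planted, 203 were recovered, and with none planted 5 overlaps arose by chance. A doubled peak density on chromosome III was called in 100 of 100 draws, and a chromosome was called in 3 of 100 draws without any excess. With peaks moved to the central part the excess was called in 100 of 100 draws, and without any in 7. With 100 peaks placed in close pairs the count of close peaks rose by 93. Simulated correlated scores gave rho = 0.372 and independent ones -0.00765. The effects planted on chromosome III and in the central part were larger than those reported below. Peaks in the chromosome and central-part draws were placed independently of each other, and simulated scores had no cap. These draws therefore give neither the power at the reported effects nor the rate of false calls for clustered peaks. Alternatives covered the overlap rule, the number of peaks taken, the background of the chromosome test, the counting of runs of close peaks, and each replicate's own list in place of the combined one.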

Results

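MAB-5 is a Hox transcription factor of C. elegans that is known to pattern the posterior body and to direct the migration of neuroblasts. As stated by its title, the study set out to identify the genomic regions bound by MAB-5::GFP in embryos. The data comprised 30000 peaks for each of 2 ChIP replicates and a combined list of 644 peaks, and the 2 input samples were not analysed here. The replicate lists reached down to scores of 0.0424 and 0.0327, with medians of 0.180 and 0.107, for replicates 1 and 2 respectively. If the score is −log10 of a false discovery rate, most of the listed replicate peaks were weak calls. The lists give no read counts, so the depth behind a peak is unknown. Of the combined peaks, 565 were 540 bp wide, 76 were narrower and 3 were wider. The combined intervals summed to 330 kb of the nuclear genome, which spanned 100.2 Mb with each chromosome taken up to its last replicate peak.

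The first 10 peaks of the combined list each met a top-score peak in both replicate lists. The combined list drew on the same replicates, so this is not an independent check. These 10 peaks are ordered here by the authors' peak number, since 272 combined peaks shared the top score. Combined peak 1 lay on chromosome III from 7784057 to 7784493 (WS220) and corresponded to peak 5 of replicate 1 and peak 2 of replicate 2. Combined peaks 4 and 6 lay beside it, at 7780419 to 7780743 and 7778534 to 7778759 of chromosome III. Combined peak 2 was on chromosome II (2995020 to 2995355), where it corresponded to peak 11 of replicate 1 and peak 4 of replicate 2. The X chromosome held combined peak 3 (8036187 to 8036566), peak 5 (11093911 to 11094298) and peak 10 (14525621 to 14525934). The remaining peaks of the first 10 were peak 7 on chromosome I (14469173 to 14469480), peak 8 on chromosome III (8446972 to 8447226) and peak 9 on chromosome V (2672691 to 2672960). Peak 8 was the lowest placed of the 10 in replicate 1, outside its first 100 peaks, and was peak 12 of replicate 2.

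The first comparison asked how far the replicates found the same regions. Among the 644 highest scoring peaks of replicate 1, 266 overlapped a peak among the 644 highest of replicate 2, a share of 41.3% (95% exact interval 37.5 to 45.2%). Random placement gave 2.34% on average and 3.73% at most, so the overlap exceeded that of randomly placed peaks (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Among nuclear peaks alone the share was 39.4%, with 0.654% by chance. With other list lengths the share was 53.0% (42.8 to 63.1%) for the 100 highest peaks, 48.8% (43.2 to 54.4%) for 322, 37.7% (34.7 to 40.8%) for 1000 and 27.1% (25.9 to 28.4%) for 5000. Over the whole lists 40.9% of replicate 1 peaks met a replicate 2 peak, against 25.1% on average in 20 random placements. Of the 644 highest peaks, 80 of replicate 1 and 67 of replicate 2 had no partner anywhere in the other replicate's list. The random placements ignore uneven coverage of the genome. Such coverage, if shared by both replicates, can also give overlap and was not assessed, as input was not analysed here.

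**Figure D1:**
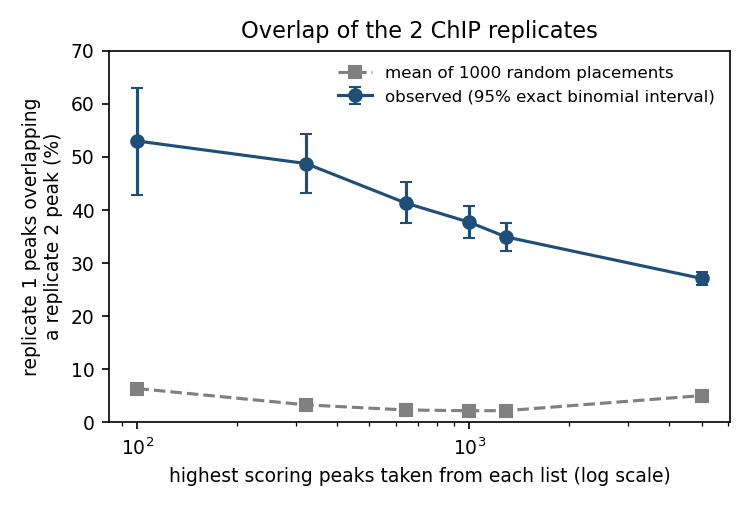
Share of replicate 1 peaks (percent, vertical axis) that overlap a replicate 2 peak when the same number of highest scoring peaks is taken from each list (horizontal axis, log scale). Blue points are observed shares with 95% exact binomial intervals and grey squares the mean of 1000 random placements. The observed share goes from 53.0% at 100 peaks to 27.1% at 5000 and lies above that mean at each.

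Most combined regions met a peak in both replicates, often at unequal peak numbers. A peak overlapping by at least 1 bp was listed for 640 of the 644 combined peaks in replicate 1 and for 644 in replicate 2. The search covered all 30000 peaks of each replicate, and its chance level was not computed. Some partners had low scores, such as 0.0432 in replicate 2 and 0.0771 in replicate 1 at the most unequal regions named below. The combined list also drew on these replicates, so a listed partner alone is weak evidence that a region was found in both. The 4 regions without a replicate 1 peak lay on chromosome V (7230787 to 7231326), chromosome I (14522889 to 14523428 and 10196921 to 10197460) and chromosome III (8658273 to 8658812). The median combined region was peak 463 of replicate 1 (quartiles 178 and 1457) and between peaks 346 and 347 of replicate 2 (quartiles 168 and 766). Among the first 644 peaks of each list, 247 combined regions (38.4%) appeared in both, 124 in replicate 1 alone, 205 in replicate 2 alone and 68 in neither. The widest gap, on a log scale of the peak number, was at chromosome I, 10235208 to 10235747, which was peak 66 of replicate 1 and peak 26157 of replicate 2. The reverse case at chromosome X, 3689388 to 3689927, was peak 24479 of replicate 1 and peak 76 of replicate 2.

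Across the 640 combined peaks found in both lists, Spearman's rho of the replicates' scores was -0.004 (two-sided permutation p = 0.917). Per the file headers the peaks passed through IDR, but how the combined set was drawn from both replicates is not given. Selection on both replicates, if made, can itself lower such a correlation. The value therefore describes this set and not how scores relate over all peaks. Pearson's r of the log scores was -0.174 (permutation p = 1e-05, the smallest that 100000 resamples can give). With 50% reciprocal overlap required, a choice fixed beforehand, rho was -0.102 over 573 peaks (permutation p = 0.0156). The capped scores hide differences among top-score regions, since 324 combined peaks met a top-score peak in replicate 1 and 263 in replicate 2. Ranked by the authors' peak number instead, the same peaks gave rho = 0.175 (permutation p = 2e-05). Over all 12249 nuclear peaks of replicate 1 that overlapped a replicate 2 peak, rho of the scores was 0.269 (permutation p = 1e-05). Peaks are not independent replicates, and the peak number and all shared peaks were chosen after the data were seen.

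The next comparison asked whether binding regions were spread evenly over the genome. Chromosomes I and III held more combined peaks than their length predicts, and chromosome V held fewer. Chromosome III had 122 peaks where 88.5 were expected (ratio 1.38, 95% exact interval 1.16 to 1.61, adjusted p = 0.000721 by the exact binomial test). Chromosome I had 123 where 96.7 were expected (ratio 1.27, interval 1.07 to 1.49, exact binomial adjusted p = 0.00969). Chromosome V had 84 where 134.4 were expected (ratio 0.625, interval 0.505 to 0.761, exact binomial adjusted p = 1.91e-06). The counts for chromosome II (93, ratio 0.948), chromosome IV (108, ratio 0.961) and the X chromosome (114, with 113.8 expected) did not differ from expectation at an adjusted threshold of 0.05. The 644 highest nuclear peaks of each replicate placed 142 and 120 peaks on chromosome III, 117 and 135 on chromosome I, and 76 and 81 on chromosome V, for replicates 1 and 2 respectively. Chromosome I did not pass in replicate 1 alone (ratio 1.21, exact binomial adjusted p = 0.0547), nor among the 322 highest scoring combined peaks (ratio 1.16, adjusted p = 0.483).

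The uneven spread was partly present among all candidate peaks. Chromosome V held 5156 of 29978 nuclear peaks in the replicate 1 list (17.2%) and 5096 of 29977 in the replicate 2 list, and 20.9% of the length. Set against the mean shares of the replicate lists, chromosome V alone passed, with 0.763 times the expected number of combined peaks (exact binomial adjusted p = 0.0330). Chromosomes I (ratio 1.14, adjusted p = 0.253) and III (ratio 1.17, adjusted p = 0.182) did not pass the exact binomial test on that background.

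**Figure D2:**
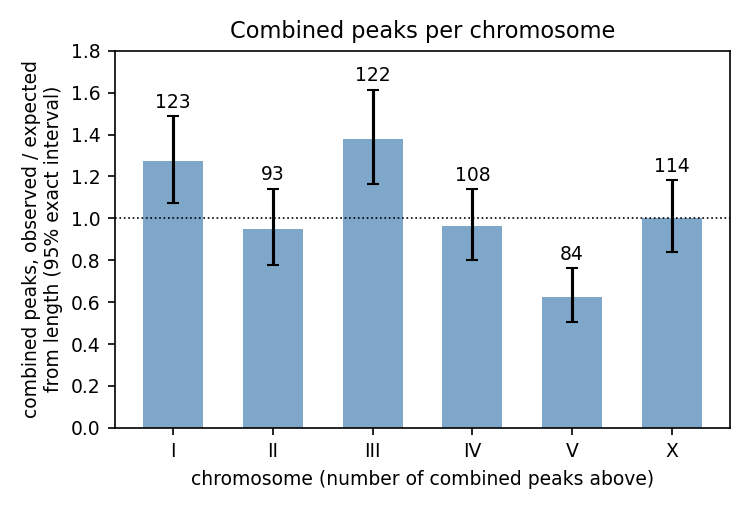
Number of combined peaks on each nuclear chromosome (horizontal axis) divided by the number expected from its length (vertical axis, no unit), with 95% exact binomial intervals as error bars and peak counts above them. The interval lies above 1 for chromosomes I and III and below 1 for chromosome V.

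Within the autosomes, combined peaks favoured the middle of the chromosome. The central 33.3% of the length held 211 of 530 autosomal peaks, or 39.8% (95% exact interval 35.6 to 44.1%, exact binomial p = 0.00199). Among the 322 highest scoring combined peaks the share was 39.0%, which did not pass (exact binomial p = 0.0595). The same part held 32.5% of the autosomal peaks in the replicate lists. Chromosome V showed the highest share, with 42 of 84 peaks in its central part (50.0%, interval 38.9 to 61.1%, exact binomial adjusted p = 0.00999). No other chromosome passed on its own, and the share was 25.9% on chromosome IV and 28.9% on the X chromosome.

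Binding regions also lay close to one another. After repeated intervals were counted once, 102 of 642 combined peaks (15.9%) had another combined peak within 5 kb. Random placement gave 41.7 peaks on average and 74 at most (one-sided permutation p = 0.001, the smallest possible). Equal numbers of peaks per chromosome drawn from the replicate lists gave 47.0 on average and 80 at most (one-sided permutation p = 0.001). Both tests of spacing were chosen after the data were seen. Some of the close peaks overlapped each other. With overlapping peaks counted once, a setting also added afterwards, the share was 12.7% (one-sided permutation p = 0.001 against random placement). The draws from the replicate lists were not repeated on that basis.

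The densest group of combined peaks lay on chromosome III and contained peak 1 of that list. A window of 40 kb on chromosome III held 9 different combined peaks between 7765861 and 7790857, and 7 of them had the top score. These included combined peaks 1, 4, 6 and 15. The next densest window, on chromosome IV, held 8 peaks between 13682651 and 13721452, all at the top score, of which combined peak 19 (13695746 to 13695988) had the lowest peak number. The densest window of randomly placed peaks held 3.90 on average and 6 at most, so both windows exceeded random placement (one-sided permutation p = 0.001). Windows with 5 peaks on chromosome III (1921100 to 1950647) and the X chromosome (1081918 to 1120851) did not (permutation p = 0.0899). Some of these peaks overlapped each other, and with overlapping peaks counted once the window at 7765861 of chromosome III held 8 separate regions (permutation p = 0.001) and the chromosome IV window 6 (permutation p = 0.006), where random placement gave 7 at most. The replicate lists were not used as background for these windows. Weak replicate peaks were also dense in the chromosome III window (percentiles 97.7 and 91.8 of that chromosome's windows in replicates 1 and 2). In the 644 highest nuclear peaks of each replicate the densest window was again on chromosome III, with 10 peaks in each and starting at 7.78 Mb in replicate 1 and 7.77 Mb in replicate 2. The replicate 1 window (7776197 to 7816196) also took in the position of the wide interval described next, so the 2 windows did not hold the same regions throughout. Overlapping peaks were not counted once in these replicate counts.

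Near this group, from 7814232 to 7816946 of chromosome III, the combined list held an interval of 2715 bp, the widest in the list. It was entered 3 times with identical ends, and its lowest peak number was 26. The corresponding intervals of 2593 bp in replicate 1 and 2663 bp in replicate 2 were entered 6 and 5 times, with lowest peak numbers of 13 and 18. Their entries had unequal scores, down to 1.06 (highest peak number 1920) in replicate 1 and 0.0647 (highest peak number 20377) in replicate 2.

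**Figure D3:**
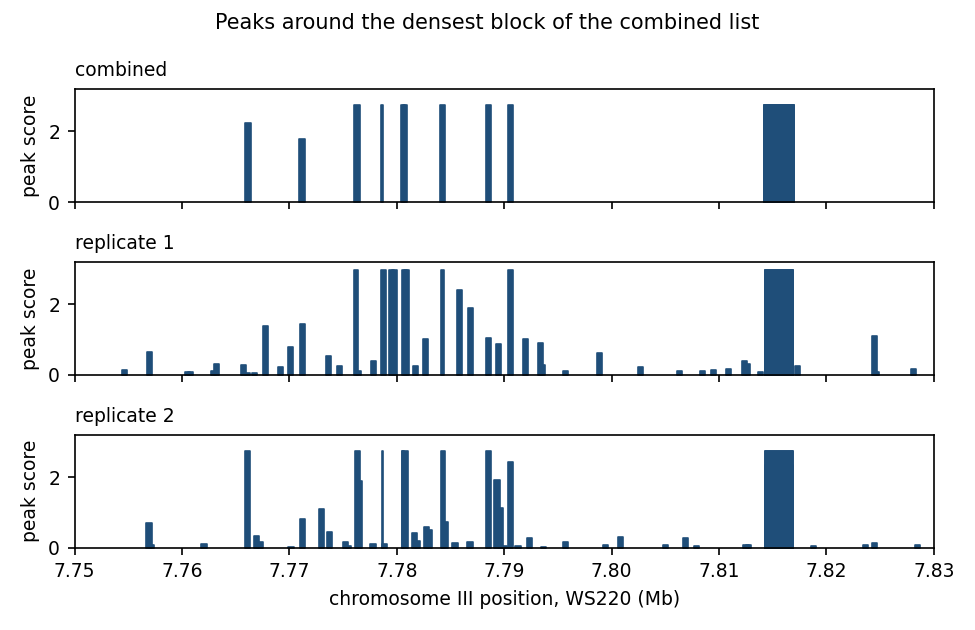
Peak intervals on chromosome III (horizontal axis, WS220 position in Mb) in the combined list and in both ChIP replicates, with the height of each bar giving the authors' peak score (vertical axis, capped within each list). Each of the 9 combined peaks between 7765861 and 7790857 met a peak in both replicates, though not always a separate or high-scoring one. Combined peaks 4 and 15 had the same lowest-numbered partner, peak 7, in each replicate. The combined peak at 7765861 met peak 9827 of replicate 1. The wide interval that starts at 7814232 in the combined list is seen in all 3 panels.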

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

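The comparison of nuclear and mitochondrial pairs was chosen after the lists had been seen, and the turning of mitochondrial positions round the molecule after the result of their random placement, which alone was set out beforehand. Mitochondrial DNA is a signal outside the combined list: 22 peaks of replicate 1 and 23 of replicate 2 lay on it, and the combined list held none. The top score of the list was carried by 18 of the 22 in replicate 1 and by 13 of the 23 in replicate 2, and 18 and 16 lay within the first 644 peaks. Peak 1 of each replicate was mitochondrial (12293 to 12635 in replicate 1, 12199 to 12779 in replicate 2), as were 7 of the first 10 peaks of replicate 1 and 4 of replicate 2. The lists held 1.64 and 1.71 mitochondrial peaks per kb in replicates 1 and 2, against 0.299 nuclear peaks per kb in each. That the nuclear densities match follows from the equal length of both lists (30000 peaks). The mitochondrial peaks together covered 54.6% of the mitochondrial span in replicate 1 and 52.3% in replicate 2. A mitochondrial count above 3, the limit that a count of 0 allows, led to this closer look.

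A candidate explanation for their absence is that mitochondrial intervals were taken out when the combined list was made. Of the nuclear replicate 1 peaks at the top score that overlapped a top-score peak of replicate 2, 99.4% (155 of 156) had a combined peak, so that nuclear peaks of this rank were rarely lost. The 13 mitochondrial ones had none, which was known beforehand and adds no test. This goes with a removal, but other ways of losing mitochondrial peaks in the combination were not tested. The nuclear exception lay on chromosome III from 502492 to 502955. That mitochondrial peaks fall at random places of an evenly covered molecule was argued against, since 11 replicate 1 positions lay within 100 bp of a replicate 2 position where 6.42 were placed so by chance (one-sided permutation p = 0.0152), and 3.65% of 1344 turns of the positions round the molecule gave as many. Uneven coverage shared by the input DNA, and binding, both stay open, because input was not analysed here.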

How the results depend on the processing

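Alternatives added after the data were seen were nuclear peaks alone, the peak number as rank (in both the overlap and the correlation), all shared nuclear peaks, the replicate lists as background, runs or repeats counted once, and those for the central part of the autosomes, close peaks, the densest block and the combined peaks found in each replicate. Of 72 alternative values, 59 were counted as unchanged. That count includes chromosome ratios that changed direction but passed the threshold in neither setting. Chromosome II, for example, went from a ratio of 0.948 to 1.03 with replicate 1 left out. The number of chromosomes that passed was also counted as unchanged where it fell from 3 to 2. Such a fall occurred among the 322 highest scoring combined peaks and with replicate 2 left out. The replicate overlap stayed above chance at each setting and list length tried (27.1 to 53.0%), the share of close peaks did likewise at each setting (8.88 to 21.3%), and the densest block held 8 to 10 peaks on chromosome III, and 8 with overlapping peaks counted once. The score correlation depended on the peaks and ranks used: rho was -0.102 (permutation p = 0.0156) with 50% reciprocal overlap, and it turned positive with the peak number in place of the score (0.175) and over all shared nuclear peaks (0.269). The last value had also been read as a test of whether choosing peaks by both lists hides a relation, and came out as that would give; it was not weighed further once seen. The count of chromosomes that passed went from 3 to 1 with the shares of the replicate lists as background. Chromosome I passed no longer among the 322 highest scoring combined peaks (ratio 1.16). The central part held 39.0% of their autosomal peaks, which missed the threshold (exact binomial p = 0.0595), as fewer peaks were tested. Requiring 50% reciprocal overlap, or positions within 100 bp, lowered the combined peaks found in replicate 1 from 640 to 580 or 579, and in replicate 2 from 644 to 589 or 620. With one replicate left out and the other's 644 highest nuclear peaks in place of the combined list, 2 to 3 chromosomes passed (chromosome I not in replicate 1), the central part held 39.3 to 43.4%, 15.9 to 16.2% of peaks were close to another, and the densest block held 10 in each; comparisons of the replicates themselves need both. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, were not analysed and no result comes from a test across samples. The gene-based chromosome background, the gene, motif and mab-5 locus results and their alternatives were not run for want of a WS220 annotation here. Depth is unknown, and the capped score leaves the strongest peaks ordered by peak number alone.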

Other observations

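Of the tests in this part, the weak-peak test of the dense block, the replicate lists as background for the chromosomes and the X chromosome tests were chosen after the values they measure had been seen in whole or in part, and counting runs once was added to the plan but set out before its result.

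The group of binding regions on chromosome III between 7765861 and 7790857 held peak 1 of the combined list. The mab-5 gene belongs to the Hox cluster of chromosome III, and the embryos carried mab-5 again as a transgene, so extra copies of a tagged segment may raise the whole block. If so, weak peaks between the binding regions should be dense as well. Weak peaks over 1000 bp from any combined peak numbered 0.584 per kb in replicate 1 and 0.539 per kb in replicate 2, against medians of 0.343 and 0.345 over 342 windows of the same width on chromosome III. These densities were at percentiles 97.7 and 91.8, and the second stays short of the 95th, so extra copies and a true cluster of binding sites cannot be told apart. Whether this block is the mab-5 locus was not determined, since no WS220 annotation was used here.

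The uneven spread over chromosomes might follow where candidate peaks can be called at all, or might come from runs of close peaks counted several times. Neither was enough for chromosome V, which stayed low against the replicate lists (exact binomial adjusted p = 0.0330) and with runs counted once (exact binomial adjusted p = 0.000264); both changes together were not tested. For chromosomes I and III the first explanation stays open, as both lost their call on that background (ratios 1.27 to 1.14 and 1.38 to 1.17). With runs counted once both passed (ratios 1.31 and 1.26). Gene density and chromatin state differ between worm chromosomes and remain untested biological explanations.

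A hypothesis from the same list is that the X chromosome may hold more of the combined peaks with the lowest peak numbers, of which the first 25 share the top score. It held 10 of the first 25 combined peaks and 104 of the other 619 (16.8%, Fisher's exact test, two-sided p = 0.00629, 0.0196 adjusted over the 6 tests made on 25 or 100 peaks of the 3 lists). Replicate 2 gave 9 of 25 against 14.1% (exact p = 0.00652, adjusted 0.0196), but replicate 1 gave 6 of 25 against 18.9% (exact p = 0.602). Over the first 100 combined peaks the share was 20 of 100 against 17.3% (exact p = 0.568). The number of 25 was picked with the order in view. The excess therefore rests on the first 25 peaks and was not seen in replicate 1 by this test, so chance remains open.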
